A study of Mus musculus with 4 samples.

How the data were processed

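Gene expression was measured in 2 droplet libraries of sorted CD4-positive, CCR7-positive mouse thymocytes, 1 from Cd4-Cre mice (WT) and 1 from Cd4-Cre mice with floxed Cgas alleles (Cgas KO), and TCR chains in 2 libraries prepared from the same genotypes. Group names come from the sample titles; how many mice went into a library is not given in the sources used here. The expression values are UMI counts per gene and barcode, deposited as unfiltered matrices that the authors made with Cell Ranger 8.0.1, per the file headers; the submitters' processing notes name Cell Ranger 7.0, Seurat 5.1.0 and the mm10 build instead, and this conflict could not be resolved. Aligner settings and gene annotation are not given in the sources used here, so no coordinates are printed. Per the labels' protocols the expression libraries used a 3' kit and the TCR libraries a TCR kit. The TCR files that the authors deposited list assembled contigs with their V and J segments, CDR3 sequence and UMI count; each contig in them was marked productive, full-length and of high confidence.

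The matrices held 588428 WT and 586687 Cgas KO barcodes over 33696 genes. A barcode was called a cell where its UMI total reached 10% of the 99th percentile of the top barcodes, their number found iteratively. This gave minimums of 1851 and 1637 UMIs and 13071 and 14889 cells, holding 88.8% and 87.7% of the UMIs. Cells with under 500 genes (2 and 3) were removed, and none exceeded 10% mitochondrial UMIs. Scrublet, run per library with an expected doublet rate of 0.06, called 1 cell and 0 cells; at 0.00765% and 0% it did not work, so doublets remain apart from that cell. As a further check, 8.93% and 9.32% of kept cells carried at least 2 productive beta chains. Kept cells had medians of 2153 and 2003.5 genes.

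Both libraries were clustered together without integration in scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (igraph implementation) were used. TCR and immunoglobulin segments, mitochondrial, ribosomal protein and sex-linked genes and Cgas were left out of the variable genes. Clusters were named from marker lists fixed before the data were examined. A name needed at least 3 of its markers, each at least 1.5-fold above the other clusters with 10 CPM added and present in at least 5% of the cluster's cells, and leading genes that did not go against it. Of 15 clusters 4 stayed unnamed: 1 with many cells that had several beta chains, 1 rich in Tnfrsf9, Ikzf2 and Tnfrsf4, 1 with few genes per cell, and 1 led by genes such as Dock2 and Maml2 in which 63.8% of cells had no beta chain. Names rest on rebuilt clusters. Those of the semi-mature CD4-like cluster and of the larger of 2 cycling-like clusters each rest on 3 of 9 markers. Mature and semi-mature CD4-like clusters together are called conventional CD4-like cells.

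Counts were summed per library and class and divided by the library's total in that class to give CPM. Exact Poisson intervals were computed for CPM, exact Clopper-Pearson intervals for shares, and exact conditional or Poisson intervals for ratios, at 95%. With 1 library per genotype, no test between genotypes was run. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs at random. Free RNA was read from barcodes with 20 to 199 UMIs, where Foxp3 stood at 14.1 CPM in WT and 11.7 CPM in Cgas KO. Log2 ratios were computed with 1 CPM added.

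The genes named in each class were the 10 highest and 10 lowest ratios among genes with at least 100 UMIs in both libraries together and at least 20 CPM in 1 of them, leaving out the gene groups listed above and gene models without a proper symbol, plus Cgas, Foxp3, Il2ra, Ikzf2, Ctla4, Ctcf, Sting1, Ccr7 and Cd4. Of each gene list, up to 4 members with the largest distance from a ratio of 1 and at least 100 UMIs could be named. The 20 lists, fixed before the data were examined, were Treg signature, recirculating Treg, Foxp3 locus regulators, CTCF and cohesin, cGAS-STING pathway, interferon-stimulated genes, TCR-induced genes, NF-kappaB targets, IL-2 and STAT5 targets, thymocyte maturation, immature single-positive thymocyte, apoptosis regulators, p53 targets, cell cycle, stress and immediate early, oxidative phosphorylation, glycolysis, helper and effector T cell, egress and migration, and other cell types. Members with at least 20 UMIs were measured, a member counted as higher or lower at a ratio of 1.2 or more or its inverse, and each median was placed among 10000 random lists of the same size matched on mean expression. Some genes stand in more than 1 list, as Ikzf2 and Il2ra do.

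Contigs were joined to cells by barcode within a genotype. Of the TCR barcodes, 97.9% in WT and 97.0% in Cgas KO were kept cells of their own genotype, and 2.21% and 1.96% matched a kept barcode of the other. Paired clonotypes were defined by the nucleotide CDR3 of both chains in cells with exactly 1 alpha and 1 beta chain and compared after drawing equal numbers of cells 100 times. Segment distances are the summed absolute differences of shares divided by 2, set against 100 shuffles of contigs. Gene neighbours and chromosomes came from a RefSeq table of assembly GRCm38.p6, matched by symbol for 25540 of the 33696 genes.

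The comparison of genes and lists was tested on simulated data. With no gene changed, counting noise put a mean of 11.4 (at most 19) of 6374 genes at least 1.5-fold apart in Treg-like cells and 0 of 6279 in conventional cells. In the Treg-like simulation 43.3% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 3-fold passed the 1.5-fold limit. In the conventional simulation 35.8%, 100% and 100% did. In either, 0 of 19 unmoved lists left the random range. Genes were drawn independently there, so this cannot show how often lists of genes that vary together would leave it. Alternatives covered the cell definition, mitochondrial limit, doublet removal, restriction to cells with both TCR chains, clustering resolution and joint or separate clustering, clustering without the Treg signature, thinning, scaling by TMM factors, UMI minimums, added CPM, and the definition of contigs and clonotypes. Figures were drawn with matplotlib 3.10.9.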

Results

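Thymocytes of mice carrying the Cd4-Cre transgene, which acts in T cells from the CD4 CD8 double-positive stage, were compared with thymocytes of mice that also carried floxed alleles of Cgas, the gene for the cytosolic DNA sensor cGAS. Cells positive for CD4 and for CCR7, a chemokine receptor of maturing thymocytes, were sorted and profiled by droplet single-cell RNA sequencing and by sequencing of the T cell receptor (TCR). There was 1 gene expression library and 1 TCR library for each of the 2 genotypes, called WT and Cgas KO here. The series asks how cGAS shapes transcription in these cells, and its title concerns regulatory T cell (Treg) development and CTCF, a protein that organises chromatin loops. With 1 library per genotype no difference has a replicate check and no test between genotypes was possible; all intervals are exact 95% intervals that cover counting error only. The WT matrix held 84763106 unique molecular identifiers (UMIs) and the Cgas KO matrix 87310091. From these, 13068 WT cells with a median of 4918 UMIs and 14886 Cgas KO cells with a median of 4433 UMIs were kept. Both libraries carried Xist RNA, at 792 and 767 CPM (UMIs of a gene scaled to a common library total), and next to no RNA of Y-linked genes.

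Cgas itself was detected at a low level in both libraries. Over all kept cells it stood at 4.48 CPM in WT (337 UMIs, interval 4.01 to 4.98) and at 2.89 CPM in Cgas KO (221 UMIs, 2.52 to 3.30), a ratio of 0.645 (0.542 to 0.766). Cycling-like cells held the most of it among the T cell classes, with 16.9 CPM in WT and 11.6 CPM in Cgas KO. Which exons lie between the loxP sites is not given in the sources used here, and a tag outside the deleted part is counted whether or not the gene is intact. The remaining UMIs therefore check neither the deletion nor the labels. Sting1, which encodes the adaptor that relays the cGAS signal, stood at 66.5 CPM in WT and 59.2 CPM in Cgas KO (ratio 0.890, 0.855 to 0.927). Ctcf stood at 159 and 172 CPM (ratio 1.08, 1.05 to 1.105).

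The first comparison concerned how many Treg cells each library held. No step separated developing from recirculating Treg cells. Cells with RNA for Foxp3, the transcription factor that defines Treg cells, made up a smaller share of the Cgas KO library. With each cell thinned to 2000 UMIs, 282 of 12928 WT cells (2.18%, 1.94 to 2.45%) and 208 of 14381 Cgas KO cells (1.45%, 1.26 to 1.66%) had a Foxp3 UMI, a ratio of 0.663 (0.552 to 0.796). Il2ra, which encodes the high-affinity IL-2 receptor chain CD25 found on Treg cells and their precursors, was detected in 2.49% and 1.92% of the same cells (ratio 0.771, 0.654 to 0.908). Ikzf2, which encodes Helios, was detected in 17.9% of WT and 19.4% of Cgas KO cells (ratio 1.09, 1.03 to 1.15), and Ctla4, which encodes an inhibitory receptor, in 7.57% and 7.89% (ratio 1.04, 0.956 to 1.14). The thinning left out 140 shallower WT cells and 505 shallower Cgas KO cells; without it the Foxp3 shares were 3.98% and 2.58%. The unthinned shares were 4.69% and 3.37% for Il2ra, 27.1% and 27.8% for Ikzf2, and 14.998% and 15.1% for Ctla4. CD8-like cells, which should lack Foxp3 and had median depths of 4756.5 and 4123 UMIs, showed a Foxp3 UMI in 0.255% and 0.210% after thinning, and an Il2ra UMI in 0.639% and 0.421%. Ikzf2 and Ctla4 were also present in CD8-like cells, at 15.5% and 23.6% for Ikzf2 and 2.55% and 4.35% for Ctla4. Over all kept cells Foxp3 stood at 13.1 CPM in WT and 8.49 CPM in Cgas KO (ratio 0.647, 0.585 to 0.715).

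Clustering gave 1 Treg-like cluster, recognised by all 9 of its fixed markers. It held 815 WT cells (6.24%, 5.83 to 6.66%) and 633 Cgas KO cells (4.25%, 3.93 to 4.59%), a ratio of 0.682 (0.614 to 0.757). Foxp3 in these cells stood at 159 CPM in WT and 138 CPM in Cgas KO (ratio 0.870, 0.774 to 0.978). That interval treats UMIs as independent, but the 762 WT UMIs came from 347 cells. Counted by cell after thinning, 26.1% of WT and 21.7% of Cgas KO Treg-like cells had a Foxp3 UMI. The ratio of these shares was 0.831 (0.664 to 1.04), an interval that includes 1. Il2ra stood at 182 and 179.98 CPM (ratio 0.987) and Ctla4 at 226 and 213 CPM (ratio 0.941). Because Foxp3 and other markers both defined the cluster and differed between the libraries, the cluster share and the marker levels within it are not independent of the clustering. Built without the Treg signature genes, the Treg-like clusters held 13.3% of WT and 12.2% of Cgas KO cells (ratio 0.922). With each library clustered on its own, the Treg-like share was 2.58% in WT and 11.4% in Cgas KO, a ratio of 4.42, with Foxp3 at 308 and 57.9 CPM in the cells so named. With mitochondrial UMIs limited to 5%, 13065 of 13068 WT and 14882 of 14886 Cgas KO cells stayed. After clustering them anew, the ratio of shares was 0.501 and that of Foxp3 levels 1.05. The lower share of cells with a Foxp3 UMI does not rest on clusters and kept its direction in the 10 alternatives that could change it, between ratios of 0.572 and 0.689.

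**Figure D1:**
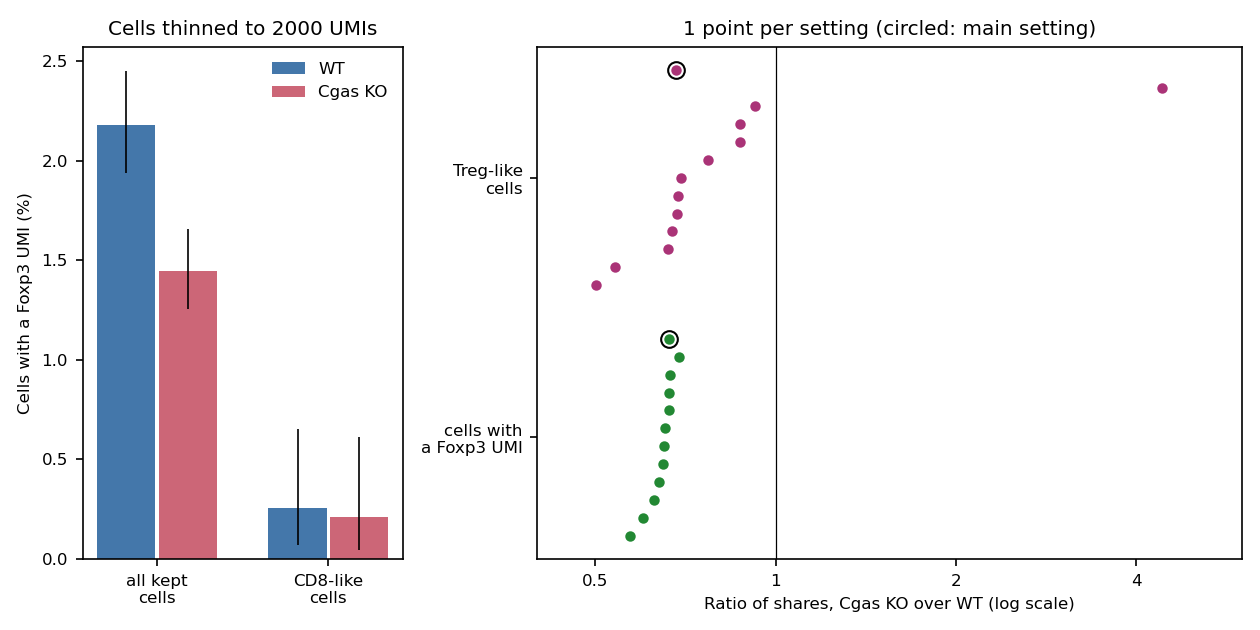
Left, the percentage of cells with at least 1 Foxp3 UMI in WT (blue) and Cgas KO (red) after thinning to 2000 UMIs per cell, over all kept cells and over CD8-like cells, with exact 95% intervals as black lines. Right, the Cgas KO to WT ratio of 2 shares on a log axis, 1 point per setting with the main setting circled: the share of cells with a Foxp3 UMI stays between 0.572 and 0.689, while that of Treg-like clusters runs from 0.501 to 4.42.

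The other cell classes described what the sort had collected. Mature CD4-like cells were 20.1% of WT and 22.0% of Cgas KO cells (ratio 1.09, 1.04 to 1.15), and semi-mature CD4-like cells 15.3% and 17.2% (ratio 1.12, 1.06 to 1.19). CD8-like cells were lower in Cgas KO, at 12.0% and 9.85% (ratio 0.821, 0.764 to 0.882), as were double-positive-like cells at 5.33% and 4.73% (ratio 0.887). Cycling-like cells were 7.95% and 8.73% (ratio 1.098), strongly TCR-signalled-like cells 6.36% and 6.15% (ratio 0.967), and dendritic-cell-like cells 0.237% and 0.242%. Cells that responded to interferon formed a cluster of 8.99% and 7.39%, whose defining genes themselves differed between the libraries. The 4 unnamed clusters made up 17.4% and 19.5%; the one in which 33.7% of cells had at least 2 beta chains held 2.30% and 4.02%, and the one led by Dock2 and Maml2 held 3.02% and 1.55%. CD8-like and double-positive-like shares depend on the CD4 and CCR7 sort gate, and all class shares on where the clusters divide.

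The next comparison asked which genes differed inside Treg-like cells. The medians of the interferon-stimulated, recirculating Treg and cGAS-STING pathway lists lay below those of random lists, and that of the immature single-positive thymocyte list above. Of 34 interferon-stimulated genes, 14 were at least 1.2-fold lower and 1 was higher, with a median log2 ratio of -0.23 that lay below all 10000 random lists matched on expression (percentile 0). Usp18, which restrains interferon signalling, stood at 56.4 CPM in WT and 34.7 CPM in Cgas KO, the antiviral gene Oas1a at 24.0 and 14.5 CPM, and Oasl2 at 26.9 and 17.8 CPM; the exception, Ifi206, stood at 5.43 and 105 CPM. The recirculating Treg list had a median of -0.42 (percentile 0; 6 of 10 members lower and 1 higher), with Cd44, an activation and homing receptor, at 44.7 and 31.5 CPM, Ahnak at 30.1 and 19.6 CPM, Ccr6, a chemokine receptor, at 31.3 and 24.3 CPM, and Itgb1 at 65.1 and 76.3 CPM. Restricted to members with at least 100 UMIs, that median was -0.19. The cGAS-STING pathway list had a median of -0.17 (percentile 0.510; 4 of 9 lower, none higher): Sting1 stood at 86.4 and 68.3 CPM, the transcription factor Irf3 at 60.8 and 43.7 CPM, the nucleotide hydrolase Samhd1 at 423 and 316 CPM, and the kinase gene Ikbke at 134 and 118 CPM. The other lower member, Ifi204, had 29 and 0 UMIs, and Cgas had 9 and 3 UMIs in this class, too few to be measured.

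The Treg signature list had a median of -0.09 (percentile 0.365; 7 of 19 lower and 2 higher). Nrp1, a surface receptor of thymus-derived Treg cells, stood at 55.9 and 35.9 CPM, Nt5e, the ectonucleotidase CD73, at 45.9 and 33.0 CPM, and Capg at 125 and 91.8 CPM, while Ikzf2 went the other way, from 1182 in WT to 1632 CPM in Cgas KO (ratio 1.38, 1.33 to 1.43). Genes of thymocyte maturation had a median of -0.13 (percentile 0; 4 of 20 lower): the MHC class I genes H2-K1 and H2-Q7 stood at 2229 and 1861 CPM and at 142 and 91.5 CPM, Il7r, the IL-7 receptor gene, at 148 and 121 CPM, and Ms4a6b at 390.0 and 324 CPM. Genes of immature single-positive thymocytes had a median of 0.17 (percentile 99.9; 5 of 15 higher and 2 lower), with Cd24a, lost as thymocytes mature, at 40.1 and 71.6 CPM (ratio 1.79, 1.47 to 2.17), Id3 at 192 and 238 CPM, Ccr4 at 15.2 and 21.7 CPM and Arpp21 at 11.5 and 15.7 CPM. The cell cycle list had a median of 0.21 (percentile 99.4; 4 of 13 higher, none lower), with Stmn1 at 60.8 and 77.8 CPM, Pcna at 51.4 and 61.5 CPM, Cks1b at 20.7 and 24.1 CPM and Top2a at 15.2 and 12.8 CPM. That median lay within the random range with members of at least 100 UMIs (0.13, percentile 95.1) and with cells thinned to 2000 UMIs (0.07, 73.0). Oxidative phosphorylation had a median of 0.10 (percentile 99.9, but 93.9 with thinned cells) with none of its 30 members 1.2-fold apart. The stress and immediate early list had a median of -0.09 (percentile 0.08; 2 of 19 lower). Regulators of the Foxp3 locus had a median of 0.09 (percentile 98.1, but 59.6 with thinned cells) although 3 of 23 members were lower and 1 higher; Nfatc2, a transcription factor downstream of the TCR, stood at 40.5 and 31.5 CPM.

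The medians of the remaining lists lay within the central 95% of random lists in Treg-like cells. They were 0.02 for CTCF and cohesin (percentile 45.6), where Ctcf stood at 147 and 133 CPM (ratio 0.903, 0.8001 to 1.02) and the cohesin subunit Smc3 at 88.1 and 107 CPM; 0.06 for TCR-induced genes (85.8); 0.03 for NF-kappaB targets (56.7); -0.07 for IL-2 and STAT5 targets (5.28); -0.05 for apoptosis regulators (10.0, but -0.14 and 1.41, below the random range, with thinned cells); 0.02 for p53 targets (53.2); 0.07 for glycolysis (92.8); 0.09 for helper and effector T cell genes (79.8); -0.03 for egress and migration (7.12), where Ccr7 stood at 872 and 948 CPM (ratio 1.09); and 0.14 for genes of other cell types (76.6, with 4 measured members). Cd4 stood at 212 and 201 CPM. In cells with a Foxp3 UMI, taken in place of the Treg-like cluster after the data were seen, the interferon, recirculating Treg, cGAS-STING, Treg signature, stress and maturation medians stayed below the random range, at -0.26, -0.29, -0.29, -0.09, -0.08 and -0.05. The cell cycle, immature thymocyte, oxidative phosphorylation and Foxp3 regulator medians, at 0.02, 0.08, 0.04 and 0.03, lay within it. NF-kappaB targets (0.10), IL-2 and STAT5 targets (0.21) and helper genes (0.26) then lay above it, and apoptosis regulators (-0.15) and genes of other cell types (-1.49) below. Of the cells with a Foxp3 UMI, 347 of 520 in WT and 226 of 384 in Cgas KO were Treg-like. A different mix of classes can therefore enter these medians.

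Single genes were compared by size. Of 6374 genes with at least 100 UMIs and 20 CPM in Treg-like cells, 43 were at least 1.5-fold higher in Cgas KO and 34 lower, against a mean of 11.4 in simulated pairs of libraries that differed by counting noise alone. The balance turned in 6 alternatives: it was 36 higher and 43 lower with TMM factors, 18 and 41 at resolution 1.5, and 22 and 31 with the 1 called doublet kept. Cells of at least 1000 UMIs gave 22 and 44, a 5% mitochondrial limit 53 and 80, and cells with a Foxp3 UMI 45 and 66. The highest ratios belonged to Ifi213, with 1 UMI in WT and 320 in Cgas KO (0.209 and 95.04 CPM, ratio interval 81.1 to 18036), and Ifi206. Next came Rnf144a, a ubiquitin ligase gene (9.19 and 33.9 CPM), Slamf6, a receptor of the SLAM family (45.9 and 106 CPM), the histone gene H4c16 (16.7 and 37.1 CPM), and Odc1, the first enzyme of polyamine synthesis (35.5 and 74.2 CPM). Tubb3 (11.1 and 23.5 CPM), Hdac9, a histone deacetylase gene (40.3 and 81.7 CPM), Tspan13 (232 and 459 CPM) and Ifi209 (69.3 and 136 CPM) completed the 10. The lowest were Kcnf1, a potassium channel gene (20.7 and 1.78 CPM), Slc15a2, a peptide transporter gene (38.6 and 7.13 CPM), Aim2, another cytosolic DNA sensor (72.0 and 23.2 CPM), Ly6k (32.2 and 11.9 CPM) and Ifi214 (74.9 and 31.2 CPM). Arhgap5 (23.8 and 9.80 CPM), Uap1 (44.5 and 19.6 CPM), the unnamed gene ENSMUSG00000121395 (23.6 and 10.7 CPM), Dynlt1b (98.96 and 48.4 CPM) and Tent5a (22.1 and 10.7 CPM) followed.

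**Figure D2:**
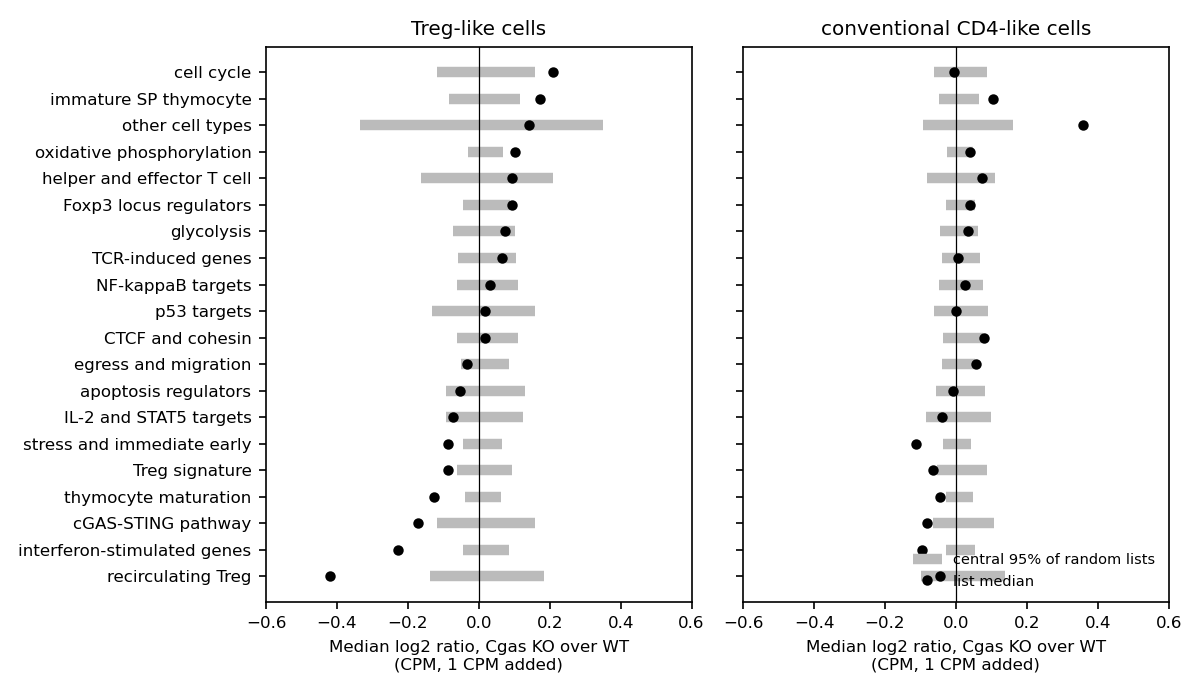
Median log2 ratio of Cgas KO over WT for each fixed gene list (black points) in Treg-like and in conventional CD4-like cells, with the central 95% of 10000 expression-matched random lists as grey bars. The interferon list lies left of its bar in both classes, at -0.23 and -0.09, and the immature thymocyte list to the right, at 0.17 and 0.10.

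Conventional CD4-like cells, the mature and semi-mature clusters together (4633 WT and 5835 Cgas KO cells), were compared to see which differences also appeared outside the Treg-like class. The medians of the stress and interferon lists lay below those of random lists, by small amounts. The stress list had a median of -0.11 (percentile 0; 3 of 19 lower and 1 higher). Its 3 lower members were the heat-shock chaperones Hspa1a (959 and 618 CPM), Hspa1b (1246 and 765 CPM) and Dnajb1 (245 and 196 CPM), while the immediate early gene Fosb stood at 6.86 and 8.90 CPM. Hspa1b was lower in each cell class, with ratios from 0.479 in dendritic-cell-like to 0.757 in cycling-like cells and 0.645 over all kept cells. Of the 34 interferon-stimulated genes, 5 were lower and 3 higher, with a median of -0.09 (percentile 0) and a mean of 0.01; Ifit3 stood at 6.20 and 4.12 CPM, Rsad2 at 1.90 and 2.84 CPM, Cmpk2 at 3.06 and 4.49 CPM, and Ifi206 at 4.88 and 73.2 CPM. The cGAS-STING list had a median of -0.08 (percentile 0.955; 2 of 11 lower), which lay within the random range with members of at least 100 UMIs (-0.04, percentile 5.09) and with thinned cells (-0.07, 3.99). It held Samhd1 at 375 and 326 CPM, Sting1 at 75.3 and 67.9 CPM, Irf3 at 56.8 and 52.9 CPM and Traf3 at 64.7 and 69.4 CPM. The 2 lower members were the targeted gene Cgas itself, at 1.78 and 1.09 CPM (43 and 29 UMIs), and Ifi204, of a gene family whose counts are uncertain, with 88 UMIs in WT and 0 in Cgas KO; Ifi204 was singled out after its values were seen. The immature thymocyte list had a median of 0.10 (percentile 99.8, but 93.2 with thinned cells; 2 of 15 higher), with Id3 at 153 and 188 CPM, Cd24a at 36.9 and 44.8 CPM, Tox at 684 and 771 CPM and Sox4 at 303 and 342 CPM. The maturation list had a median of -0.05 (percentile 0.470; 2 of 20 lower and 1 higher), with H2-K1 at 1405 and 1207 CPM, H2-Q7 at 67.4 and 41.5 CPM, Ly6c1 at 21.0 and 15.6 CPM and Klf3 at 84.6 and 103 CPM.

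The Treg signature list also had a lower median in conventional cells, -0.06 (percentile 1.11; 6 of 18 lower and 3 higher). Izumo1r, the folate receptor FR4, stood at 295 and 224 CPM and Nt5e at 5.71 and 2.32 CPM, while Ikzf2 stood at 29.5 and 36.0 CPM and Ctla4 at 41.4 and 48.9 CPM. Foxp3 was at 2.65 and 2.36 CPM and Il2ra at 2.65 and 1.87 CPM. CTCF and cohesin genes had a median of 0.08 (percentile 98.1, but 90.3 with thinned cells) with none of 14 members 1.2-fold apart; Ctcf stood at 145 and 153 CPM (ratio 1.06, 1.01 to 1.105). Egress genes had a median of 0.06 (percentile 98.2, but 93.9 with thinned cells), with Ccr7 at 628 and 711 CPM (ratio 1.13) and S1pr1, the receptor that guides exit from the thymus, at 200.01 and 228 CPM. Genes of other cell types had a median of 0.36 (percentile 100), which became 0.14 (percentile 88.8, within the random range) without 2 Cgas KO cells full of haemoglobin RNA, 3.37 over the 6 members with at least 100 UMIs and 3.15 with thinned cells (7 members). Within the central 95% of random lists lay recirculating Treg genes (-0.05, percentile 14.8), Foxp3 regulators (0.04, 92.0, but 0.08 and 99.2, above that range, with thinned cells), TCR-induced genes (0.01, 36.9), NF-kappaB targets (0.03, 67.6, mean -0.02), IL-2 and STAT5 targets (-0.04, 15.8), and apoptosis regulators (-0.01, 29.2). So did p53 targets (-6.01e-05, 34.2, mean 0.01), the cell cycle (-0.0046, 31.3, mean 0.03), oxidative phosphorylation (0.04, 94.0), glycolysis (0.03, 85.5) and helper genes (0.07, 89.1). Cd4 stood at 290 and 295 CPM. Percentiles among random lists describe these libraries and are not tests of the genotype.

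Of 6279 genes in conventional cells, 17 were at least 1.5-fold higher in Cgas KO and 14 lower; the simulated noise gave 0. This balance turned too, as at 15 and 18 with cells of at least 1000 UMIs and 22 and 54 with each library clustered on its own. The highest were Ifi213 (0.744 and 94.1 CPM), Ifi206, Slamf6 (24.1 and 64.2 CPM), Ifi208 (60.9 and 114 CPM), Atf6, a sensor of endoplasmic reticulum stress (11.9 and 22.1 CPM), H4c16 (19.8 and 34.8 CPM), Ifi209 (56.7 and 97.8 CPM) and Btaf1 (53.3 and 91.1 CPM). The haemoglobin genes Hbb-bs (1.37 and 148 CPM) and Hbb-bt (0.538 and 20.4 CPM) were also among the highest, and a single cell held 50.3% of the Hbb-bs UMIs. The lowest were Slc15a2 (26.0 and 3.44 CPM), Aim2 (42.1 and 9.35 CPM), Ly6k (30.2 and 10.999 CPM), Klhdc2 (74.1 and 33.8 CPM), the unnamed gene ENSMUSG00000095041 (97.6 and 45.7 CPM), Dynlt1b (93.9 and 44.4 CPM), Mid1 (29.8 and 16.3 CPM), Ifi214 (43.0 and 23.9 CPM), Arhgap5 (26.8 and 15.04 CPM) and ENSMUSG00000121395 (24.4 and 14.03 CPM). Both classes shared 12 of the higher genes and 10 of the lower ones. Of the 22, 19 had a position: 7 lay on chromosome 1 in the GRCm38.p6 annotation (Atf6, Slamf6, Aim2, Ifi206, Ifi209, Ifi213 and Ifi214), 3 on chromosome 12 (Arhgap5, Churc1 and Strn3) and 3 on chromosome 17 (Dynlt1b, H2-Q7 and Hspa1a), and none of the 19 on chromosome 9, where Cgas lies. Of the 20 genes named above for their ratio in Treg-like cells, 7 lay on chromosome 1 and 6 on chromosome 12 (Arhgap5, Hdac9, Kcnf1, Odc1, Rnf144a and Tspan13), which held 6.002% and 3.57% of the measured genes; Tent5a, 1 of the 20, lay on chromosome 9. Genes of the Ifi200 family (Aim2, Ifi204 and the genes numbered Ifi206 to Ifi214) belong to a multigene family, as do H2-Q7 and Hspa1a. No sequences were compared here; where members are alike, counting could have split their reads, so these values are uncertain.

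**Figure D3:**
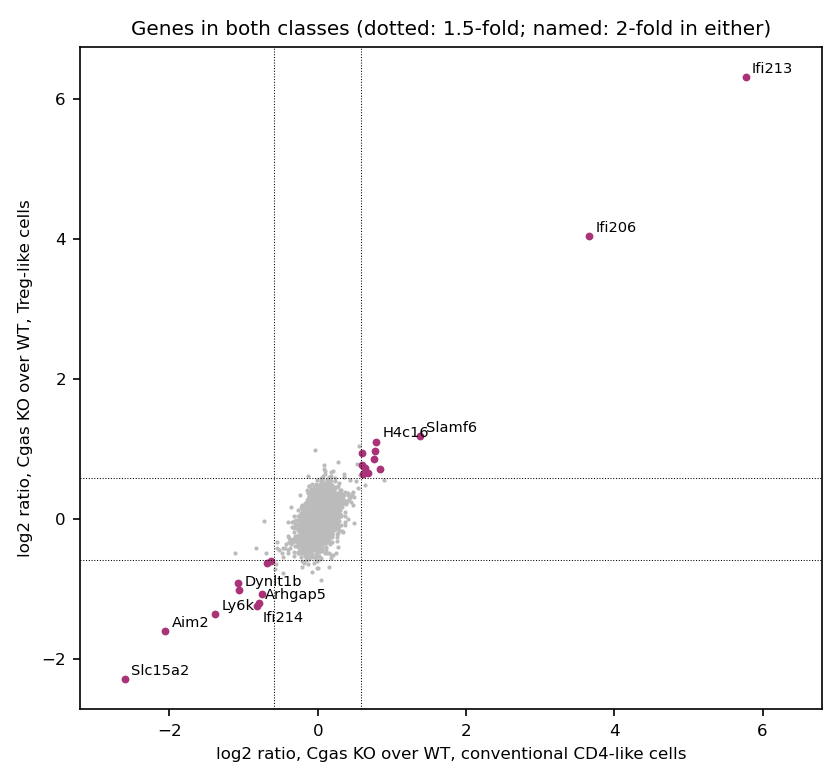
Log2 ratio of Cgas KO over WT in conventional CD4-like cells (horizontal) and Treg-like cells (vertical) for 5983 genes measured in both, 1 point per gene. The 22 genes at least 1.5-fold apart in the same direction in both classes are purple, with Ifi213 and Ifi206 at the upper right and Slc15a2 and Aim2 at the lower left.

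The last comparison concerned the TCR. A productive alpha and beta chain was found in 82.7% of kept WT cells (82.0 to 83.4%) and 82.5% of Cgas KO cells (81.8 to 83.1%), at least 2 alpha chains in 14.1% and 14.4%, and at least 2 beta chains in 8.93% and 9.32%. Cells with no TCR contig were 7.25% and 6.35% (ratio 0.877, 0.801 to 0.961). Treg-like cells had both chains in 77.9% of cells in either library. The invariant chain of natural killer T cells occurred in 7 WT cells (0.0536%) and 11 Cgas KO cells (0.0739%), 5 and 7 of them cycling-like. None of the 645 and 503 Treg-like cells with an alpha chain had it. The exact intervals of these shares reach up to 0.570% and 0.731%. Of 150 segments with at least 100 contigs, 8 were at least 1.2-fold higher in Cgas KO and 11 lower. TRAV19 had the lowest ratio, 1.06% of alpha contigs in WT and 0.644% in Cgas KO (ratio 0.609, 0.463 to 0.799), and TRAV7N-6 the highest, 0.830% and 1.24% (ratio 1.49, 1.17 to 1.92); TRAV genes form families, so such shares are uncertain where members are alike. The J segments with the lowest ratios were TRAJ57, at 2.36% and 1.73%, and TRAJ53, at 1.67% and 1.17%; these segments were singled out after their values were seen. The summed distance between the genotypes' segment shares was 4.77% for TRAJ and 3.37% for TRBV, above the highest of 100 shuffles (3.996% and 3.14%), and 4.92% for TRAV and 1.75% for TRBJ, below it (5.27% and 2.42%). The shuffles hold counting noise alone and treat contigs as independent. Contigs of all kept cells were pooled, so a different mix of classes can enter these distances. With barcodes that shared all their TCR chains counted once, chosen after the data were seen, the distances were 4.96% for TRAJ and 3.32% for TRBV, against highest shuffles of 4.19% and 2.96%. CDR3 length averaged 13.5 amino acids in alpha chains of both genotypes and 13.9 in beta chains.

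Repeated receptors separated the libraries. Among barcodes with exactly 1 alpha and 1 beta chain, 0.415% of 8428 in WT and 13.3% of 9605 in Cgas KO shared their paired nucleotide clonotype with another barcode of their library. Nearly all repeats in Cgas KO were pairs of barcodes of low depth (0.644 times the median UMIs of their cluster), so whether they are separate cells is open and they are not read as clonal expansion. Drawn down to 8428 barcodes, the Cgas KO share was 11.7% (11.1 to 12.2% over 100 draws), and no clonotype occurred in both genotypes. Before drawing, the shares in Treg-like cells were 0% of 459 WT barcodes and 9.32% of 365 Cgas KO barcodes. They were 0.520% and 11.1% in conventional CD4-like cells and 0.370% and 9.49% in CD8-like cells. At equal numbers the conventional Cgas KO share was 8.95% (8.02 to 9.79% over 100 draws) and the CD8-like WT share 0.343%. Within each genotype, the TRAV, TRAJ and TRBJ distances between Treg-like and conventional cells lay within 100 shuffles. The TRBV distance was 9.17% in WT, barely above the highest shuffle (9.11%), and 10.49% in Cgas KO, within them (highest 10.53%).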

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

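Several alternatives were chosen after the data were seen. They included thinning before clustering, counting barcodes that share all TCR chains once, and leaving out cells with extra chains or haemoglobin-rich cells. The unnamed cluster led by Dock2 and Maml2 and the Ifi200 family were also left out, each in its own alternative. The rest were the CD4-lineage denominator, averaging over all thinnings, and taking cells with a Foxp3 UMI as the Treg class. Of 70 alternative values for the main results, 51 stayed, 17 moved and 2 reversed. Of 218 for list medians, 206 stayed, 12 moved and 0 reversed. Of those that stayed, 11 and 41 were identical to the main value, as where the setting touched none of the cells or genes counted, which says nothing of stability. No list median was computed with the cells clustered anew, so its counts say nothing of shifts in the Treg-like boundary. A ratio stayed when it lay inside the exact 95% interval of the main value, and a count when within 1.5 times it. A share of repeated clonotypes stayed when inside the exact 95% interval of the mean Cgas KO share over the main draws. A list median stayed when it shifted by no more than the distance from the middle to the edge of the central 95% of random lists. A median that stayed could still enter that range. Of 19 medians outside it, 7 entered and 2 others left when each cell was thinned to 2000 UMIs, leaving 14. In Treg-like cells those entering were Foxp3 regulators (percentile 59.6), cell cycle (73.0) and oxidative phosphorylation (93.9), and in conventional cells CTCF and cohesin (90.3), cGAS-STING (3.99), immature thymocyte (93.2) and egress (93.9). Those leaving were apoptosis regulators in Treg-like (1.41) and Foxp3 regulators in conventional cells (99.2). Members with at least 100 UMIs left 17 and the removal of haemoglobin-rich cells 18, while TMM factors and leaving out the Ifi200 family ended no call. With cells holding a Foxp3 UMI, 4 of 10 entered and 5 others left. The share of cells with a Foxp3 UMI stayed between ratios of 0.572 and 0.689 in 10 alternatives; a minimum of 1000 UMIs could not change it, because thinning to 2000 UMIs drops the added cells. The Treg-like share, 0.682 at the main setting, depended on where the cluster boundary fell. Cells with at least 1000 UMIs gave a ratio of 0.870 for the share and 0.746 for the Foxp3 level in the class. A 5% mitochondrial limit, which kept 13065 WT and 14882 Cgas KO cells, gave 0.501 and 1.05, the latter reversed. It put 133 genes at least 1.5-fold apart in place of 77. Keeping the 1 called doublet gave 0.870 and 0.738, so a single added cell moved the boundary. Resolution 1.5 gave 0.772 and 0.773, and resolution 0.6 gave no Treg-like cluster and so no value. Each library clustered on its own gave 4.42, reversed, and 0.188, with 877 genes apart in the Treg-like and 76 in the conventional class in place of 31; clusters were then named separately. Leaving the Treg signature out of the clustering gave 0.922 for the share, and thinning before clustering 0.540. In Treg-like cells, restriction to cells with both TCR chains gave 124 genes, a minimum of 500 UMIs 17, as fewer genes were then eligible, and 10 CPM added 31, as the added CPM shrinks ratios of low genes; TMM factors gave 79 with 36 higher and 43 lower, against 43 and 34, a balance that also turned in 5 other alternatives. Lowering the minimum to 20 UMIs changed no count, because the CPM minimum already excluded those genes. Repeated clonotypes in Cgas KO were 10.9% rather than 11.7% when only kept cells were used. With barcodes that share all TCR chains counted once, TRAJ and TRBV distances between genotypes were still above their highest shuffle, and TRAV and TRBJ distances below it. Where no reason is given, the cause was not tested. No paired analysis was possible because each genotype had 1 library per assay. Depth limits low genes most: Cgas had 12 UMIs in Treg-like cells of both libraries together.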

Other observations

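Some differences reached beyond the Treg-like and conventional classes. In CD8-like cells Ikzf2 stood at 134 CPM in WT and 220.3 CPM in Cgas KO (ratio 1.65, 1.53 to 1.78), Ctla4 at 13.99 and 24.7 CPM (ratio 1.77, 1.39 to 2.26) and Ccr7 at 437 and 592 CPM (ratio 1.35, 1.29 to 1.42). Ctla4 was also higher in strongly TCR-signalled-like cells, at 25.1 and 35.8 CPM (ratio 1.43, 1.13 to 1.81), while Ikzf2 there stood at 879 and 900.0 CPM. Sting1 was lower in CD8-like cells at 50.3 and 40.9 CPM (ratio 0.813, 0.697 to 0.949) and in mature CD4-like cells at 85.7 and 75.1 CPM (ratio 0.876, 0.805 to 0.953); no difference was detectable in double-positive-like cells (ratio 0.743, 0.532 to 1.03). Ctcf in double-positive-like cells stood at 242 and 303 CPM (ratio 1.25), but the 2 clusters of this class were mixed differently, with 620 and 570 cells in one and 77 and 134 in the other. Within them the Sting1 ratio was 0.740 and 1.35, opposite in direction, and 0.823 (0.587 to 1.15) over both. Within each, the Ctcf ratio was 1.14 (0.994 to 1.29996) and 1.13 (0.985 to 1.298), and over both clusters, each compared with itself, 1.13 (1.03 to 1.25). A cluster left unnamed, rich in Tnfrsf9, Ikzf2 and Tnfrsf4 and with a Foxp3 UMI in only 1.19% of its cells held 10.7% of WT and 12.1% of Cgas KO cells.

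The tests of a strain segment, of Cgas loss inside T cells alone, of sister cells and of contigs at a wrong barcode were chosen only after the result was seen, as were the alternatives of thinning before clustering and counting shared barcodes once.

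The 22 genes at least 1.5-fold apart in both classes went the same way elsewhere: of the 12 higher and 10 lower genes, 10 and 10 did so by 1.2-fold in double-positive-like and 11 and 10 in CD8-like cells. Of the 19 genes with a position, 57.9% had another of the set within 20 measured genes on either side. Random sets had an upper bound of 33.3% for their central 95% and a mean of 11.04%. The share measures the pattern itself, so it does not test for a segment from another mouse strain, which stays open. Without tandem families 25.0% of 8 genes had such a neighbour, under the 28.6% bound of random sets. This leaves reads shared within families open, as 8 genes give little power. Besides Ifi200 genes, the step left out Slamf6, H2-Q7, Hspa1a, Dynlt1b, Ly6k, Tubb2a and H4c16, each alone of its family in the set. The lower share therefore need not reflect shared reads. Wider sets without those families gave 35.0% of 40 genes in Treg-like cells (bound 39.5%) and 16.7% of 12 in conventional cells (33.3%). In either class it was 40.9% of 44, level with its 40.9% bound and against a mean of 23.5%. These wider sets placed only 62.9 to 70.6% of their genes, too few to decide. Loss of Cgas inside T cells alone could not be judged. The least level it required of the lower genes in dendritic-cell-like cells came to -197 CPM, which no count can break. Those genes together stood at 1149.6 and 693 CPM there. Hspa1a alone made up most of their sum in WT conventional cells, so the sum says little of the others. Only 4 of the 10 were measured, and 51.6% and 50% of the dendritic-cell-like cells held both TCR chains. Neither strain nor mapping was measured, so for the 22 genes they cannot be told apart from an effect of Cgas.

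The lower Treg-like share in Cgas KO might come from lower depth per cell or from cells counted under 2 barcodes. Thinning every cell to 2000 UMIs before clustering left a ratio of 0.540 with an interval below 1. This argues against lower depth as the whole cause. Counting barcodes that share all TCR chains once left 0.694. That step kept 14207 of 14886 Cgas KO barcodes, too many for the ratio to reach 1 whatever the class of those dropped. The pairs it found were thus too few to explain the lower share. Pairs whose barcodes did not hold the same chains were not found, so cells under 2 barcodes stay open. Both values share the instability of the cluster boundary, which turned the ratio to 4.42 when libraries were clustered apart. The ratio for cells with a Foxp3 UMI, free of clusters, was 0.664 with shared barcodes counted once. That step could not bring it to 1 either. The genotype cannot be told apart from the mouse, the sort or the library, because there was 1 library per genotype. Fewer Foxp3-expressing thymocytes without Cgas remains a hypothesis that replicate mice would test.

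The repeated clonotypes of the Cgas KO library were nearly all pairs: 577 paired clonotypes were found under exactly 2 kept barcodes and 0 under 3 or more, against 16 pairs in WT. Expression correlated within pairs at a median of 0.362, above the highest of 100 sets of random pairs from the same clusters with like UMI totals (0.309), which is consistent with 1 cell under 2 barcodes, as when a droplet holds 2 beads; the summed UMIs of a pair, at a median of 5893 against 4565.5 for a single other barcode, exceeded those of 1 barcode. The 16 WT pairs were alike in correlation, at 0.348 (highest random 0.315), in depth, at 0.539 times the cluster median UMIs, and in place. Of them, 81.2% fell in 1 cluster (random at most 56.2%). Their summed UMIs, at a median of 4886 against 4923 for a single other WT barcode, did not exceed those of 1 barcode. In WT, 1 clonotype was found under 3 or more barcodes. Cgas KO barcodes in pairs held 0.644 times the median UMIs of their cluster, less than sister cells of usual depth would. Sister cells of lower depth would give this too, and the sum of a pair exceeded 1 barcode, so depth leaves sister cells of 1 clone open. Contigs given to a wrong barcode are argued against by place, since 86.5% of pairs fell in 1 cluster against at most 18.2% of random pairs. No biological explanation other than sister cells was tested, and counting barcodes that share all their TCR chains once leaves 14207 Cgas KO and 13045 WT cells, the number on which shares would rest if each pair were 1 cell.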
